A study of Arabidopsis thaliana with 9 samples.

How the data were processed

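RNA from 9 samples of Arabidopsis seedlings was hybridised, 1 sample per array, after biotin labelling of cRNA, per the labels' protocols. The values used were the log2 expression values of the deposited series table, which the authors had made with RMA per the submitters' processing notes. RMA corrects the background, normalises the arrays to a common distribution and summarises the probes of each set on the log2 scale. No version of RMA is given in the sources used here, and limma is named in the same notes without its settings. The range of the values, about 2.0 to 13.4, fits a log2 scale, and the array medians were 4.47, 4.52 and 4.50 for cPTIO replicates 1 to 3, 4.51, 4.51 and 4.49 for SNP and 4.55, 4.54 and 4.60 for the control. The scanner images were not used here, so detection calls per probe set and the scan batches are unknown. Because RMA gives the arrays nearly the same distribution, a change in the total amount of RNA per seedling cannot be seen.

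Groups and replicate numbers were taken from the sample titles. Of the 22810 probe sets, 64 manufacturer's controls were kept out of the tests and described separately, which left 22746. Names came from the platform's probe table. In it 13513 probe sets had 1 gene, 503 had several and were left unnamed, and 8730 tested probe sets were not listed and are unnamed here. Through the gene identifier 13436 of the 13513 matched a gene of the RefSeq table of assembly TAIR10.1, covering 13286 loci, and that table was used for names alone. No genome build is given in the sources used here, so no coordinates are printed. NIA1, NIA2, GSNOR1 and AHB1, which were to be named in every comparison, had no named probe set and are not analysed here. Of the 94 probe sets with the widest called differences, leading in a list or in a list too small to test, 1 ended in _s_at or _x_at, a mark of probes that can bind several transcripts. For AT1G74770 a second, dimmer probe set gave log2 fold changes of -0.38 with SNP and -0.27 with cPTIO against the control.

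Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) as a model of 3 group means over all 9 arrays, with 6 residual degrees of freedom, 2-sided tests and Benjamini-Hochberg adjustment over the 22746 probe sets within a comparison at a threshold of 0.05. Errors of fold changes are limma's standard errors, and the 3 groups share 1 estimate of the spread. The moderated F test covered the 3 groups at once. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none is reported for single values.

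Before the data were examined, 32 gene lists with 702 loci were fixed, of which 114 loci were measured under a single name. The 9 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene, the one with the highest mean, and with adjustment over the 9 lists of a comparison. Camera compares a list with all other genes, whereas fry, run beside it, asks whether the genes of a list move on balance 1 way. No list passed with an estimated correlation in any of the 3 comparisons. In fry the iron deficiency list passed in cPTIO against the control, and the hypoxia, phenylpropanoid and iron deficiency lists in SNP against cPTIO. Another 17 lists had 1 to 4 measured genes and were only counted, and 6 had 0. The genes named in the text were set by a rule fixed at the same time. It takes, per comparison, the 8 largest rises and 8 largest falls among called probe sets with 1 gene and no overlap between the arrays of the groups, and then up to 4 called members of each list described, or the member with the widest difference where none was called.

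The correlation of the 2 sets of fold changes against the control was set beside 100 simulations in which each group kept its own spread per probe set and had no change. A further 1000 simulations gave the deviations of whole arrays from their group means random weights, the same for SNP and cPTIO arrays of a number, so that the correlation between genes and the pairing were kept. Overlaps of calls were set beside the product of the 2 counts divided by the number of probe sets tested. The same functions were tested on simulated data with 200 changed probe sets per comparison. Of 100 changed 2-fold, 66, 73 and 70 were recovered in SNP against control, cPTIO against control and SNP against cPTIO, and of 100 changed 4-fold, 96, 93 and 92, with 10, 7 and 12 false calls among 22746 probe sets. A list of 16 genes shifted by a log2 value of -1 in SNP against cPTIO was found in 20 of 20 simulated sets with 13286 genes, and 3 of 160 tests of unshifted lists were called. These simulated data drew genes and arrays independently, with the same spread in all groups. They therefore cannot show how the tests do with correlated genes, paired arrays or groups of unequal spread.

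Whether arrays with the same replicate number belong together is not stated in the labels. The deviations from the group means of the same-numbered SNP and cPTIO arrays correlated across probe sets at 0.26, 0.30 and 0.42 for replicates 1, 2 and 3. With another number the highest values were 0.12, 0.19 and -0.30. Deviations cancel out within a group, so one shared by the replicate 3 arrays also raises the values among replicates 1 and 2. The numbers were taken to pair SNP and cPTIO in some checks, while the main fit left the arrays unpaired. For SNP and the control the same-number values were 0.13, -0.02 and 0.08, and for cPTIO and the control 0.06, 0.06 and -0.01, so the control was not taken as paired.

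Alternatives fixed before the data were examined were the replicate number as a block, a second quantile normalization, centring each array on its median, leaving out the 40% of probe sets with the lowest mean, fitting only the arrays compared, eBayes with a trend and with robust estimation, array weights, a minimum of 2-fold, fry, an estimated correlation, averaging all probe sets of a gene, and leaving out each array in turn. The block on the 6 SNP and cPTIO arrays alone and the removal of replicate 3 of both treatments were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.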

Results

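Transcript levels were measured on 9 Affymetrix-type arrays hybridised with RNA from Arabidopsis thaliana seedlings of the Columbia-0 accession, collected at an age of 8 days. Sodium nitroprusside (SNP) is a compound that releases nitric oxide (NO), and cPTIO is a compound that scavenges it. The labels describe 3 arrays of untreated seedlings, called the control, 3 arrays of seedlings exposed to SNP and 3 arrays of seedlings exposed to cPTIO, each from a separate biological replicate. Treatment began after 3 days of growth and lasted 5 days in sealed dishes. The 100 uM SNP solution stood in an open donor dish beside the seedlings, so that its volatile products reached them through the air, whereas the 1 mM cPTIO solution was added to the dishes that held the seedlings. The study design calls the control SDW, without spelling it out, and what the control dishes held is not given in the sources used here. The table held 22810 probe sets, of which 22746 were tested and 64 were manufacturer's controls. The array medians lay between 4.47 and 4.60 on the log2 scale, and the 3 arrays per group limit the precision of every value.

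The control arrays stood apart from the 6 treated arrays in the seedling transcripts and also in 1 hybridisation control. On the first principal component, which held 32.4% of the variance, the control arrays scored from -40.0 to -32.5 and the treated arrays from -0.06 to 37.3. Within groups the arrays correlated at 0.987 to 0.993 across probe sets in the control, at 0.986 to 0.994 with SNP and at 0.963 to 0.989 with cPTIO. The cPTIO replicate 3 array accounted for the low end, with its correlations to the other cPTIO arrays at 0.963 and 0.972. The bioC probe sets detect a bacterial transcript added to every hybridisation, and their mean signal was 6.32 ± 0.18 (SD, n = 3) on the log2 scale in the control, 8.53 ± 0.09 (SD, n = 3) with SNP and 8.36 ± 0.51 (SD, n = 3) with cPTIO. The bioB, bioD and cre probe sets, which detect the other added transcripts of that kind, differed between treated and control arrays by 0.35, 0.21 and 0.13 on the log2 scale. Of 5 further families of bacterial control probe sets, dap, thr, phe and lys were higher in the treated arrays by 1.00, 0.51, 0.42 and 0.23 and trp by 0.03. Only for bioC did the ranges of all treated and all control arrays not overlap. The SNP arrays taken alone also lay above every control array in bioB, bioD, cre, dap, thr and phe, but not in lys or trp. For cre they lay at 12.21 to 12.30, against 11.98 to 12.15 in the control. Whatever set the control hybridisations apart cannot be told apart from the absence of treatment in any comparison with the control.

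**Figure D1:**
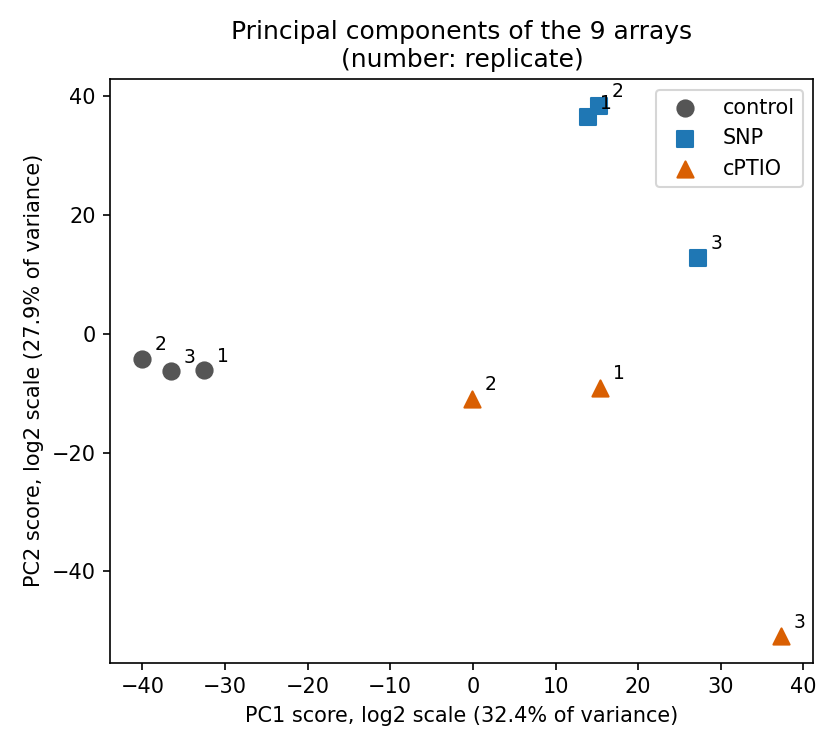
Scores of the 9 arrays on the first (horizontal) and second (vertical) principal components of the log2 values of 22746 probe sets, with the share of variance on each axis; symbols mark the groups and numbers the replicates. The 3 control arrays lie between -40.0 and -32.5 on the first component, and cPTIO replicate 3 lies lowest on the second at -50.9.

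**Figure D2:**
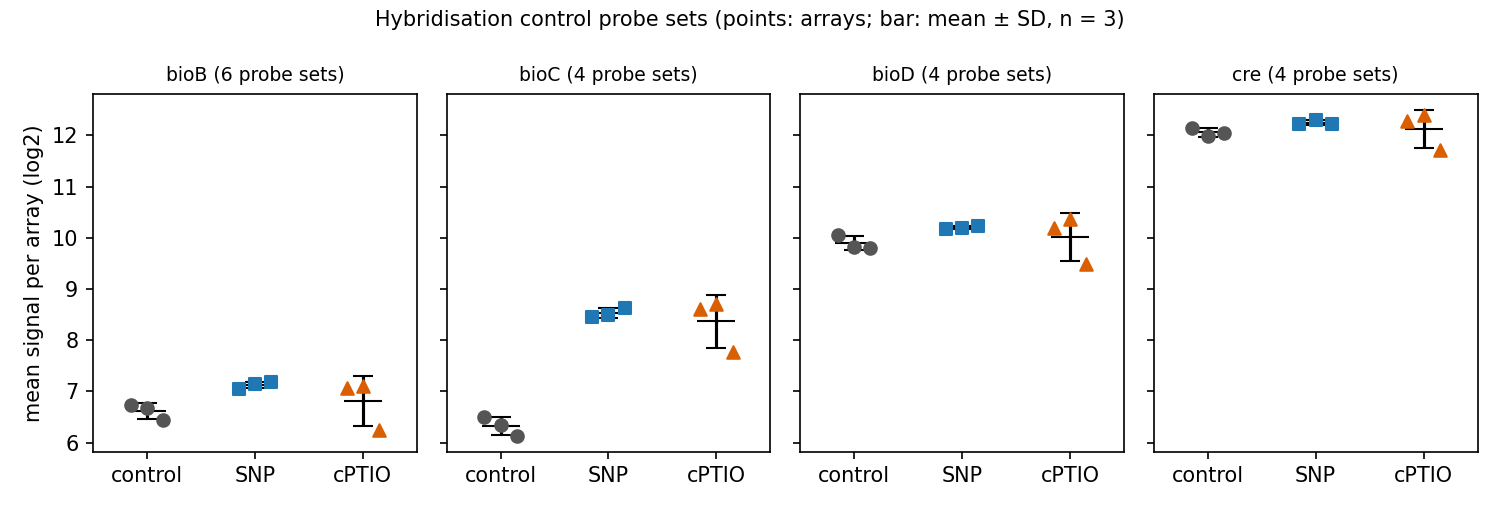
Mean log2 signal per array (vertical) of 4 families of hybridisation control probe sets in the 3 groups (horizontal); points are arrays and bars the mean ± SD with n = 3. The bioC signal is 6.14 to 6.50 in the control arrays and 7.77 to 8.71 in the treated arrays, while the means of the other 3 families differ by 0.13 to 0.35 between treated and control arrays.

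The comparison of SNP with the control asks which transcripts differ in seedlings kept beside an NO donor. AT2G47780, a rubber elongation factor family protein of lipid droplets, rose from 4.35 ± 0.47 to 8.93 ± 0.73 on the log2 scale (SD, n = 3 each), a log2 fold change of 4.58 ± 0.59 (SE). ICL (AT3G21720), the isocitrate lyase of the glyoxylate cycle, rose by 3.07 ± 0.65 and MGL (AT1G64660), a methionine gamma-lyase, by 2.86 ± 0.43. AT3G28220, a TRAF-like protein, rose by 3.65 ± 0.27, AT1G52000, a lectin, by 2.70 ± 0.53, AT1G73120 by 2.60 ± 0.24, AT4G14090, the anthocyanin glucosyltransferase UGT75C1, by 2.41 ± 0.47, and JRG21 (AT3G55970), a jasmonate-regulated oxygenase, by 2.39 ± 0.26. Among the falls, AT4G33720, of the PR-1-like family, fell by 3.83 ± 0.65 on the log2 scale, AT5G40590 fell by 3.37 ± 0.70, the acyltransferase family member AT4G15390 fell by 3.22 ± 0.43, and AT4G16260, a beta-glucanase family member, fell by 3.21 ± 0.25. The class III peroxidase AT4G11290 fell by 3.01 ± 0.36, AT1G14960 of the major latex protein family fell by 2.85 ± 0.25, the cupin AT4G36700 fell by 2.84 ± 0.63, and AT5G62360, a pectin methylesterase inhibitor family member, fell by 2.84 ± 0.28. The limma adjusted p values of these 16 genes lay between 0.00138 and 0.0363. The genes were taken from called probe sets without overlap between the arrays of the 2 groups, so neither property is a separate result. Of all probe sets tested 29.9% had no such overlap, where 10% would by chance. For 10 of the 16 the call held with each of the 9 arrays left out. ICL, AT1G52000 and AT4G14090 lost it without SNP replicate 1 or 2 or any control array, with adjusted p values of up to 0.115, 0.0960 and 0.0861. AT4G33720 lost it without SNP replicate 1 or 2 or control replicate 2 (up to 0.0608), AT5G40590 without any SNP or control array (up to 0.0969), and AT4G36700 without any of these 6 or cPTIO replicate 2 (up to 0.139). Without SNP replicate 3 the log2 fold changes of AT1G52000, AT4G14090 and AT4G36700 were 3.43, 3.01 and -2.15, each a shift of over 1.5 times in fold.

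Of the lists of genes fixed before the data were examined, 3 passed the set test in SNP against the control, all with a preset correlation between genes. The phenylpropanoid, flavonoid and anthocyanin list had 8 of its 25 genes measured, with a median log2 fold change of 1.32 and positive values in 7 of the 8. Per array their mean deviation was 1.22, 1.53 and 0.14 in SNP replicates 1, 2 and 3 and -0.27, 0.25 and -0.31 in control replicates 1, 2 and 3, so that the groups overlapped. AT4G14090 rose and the other 7 did not pass over all probe sets, whereas 5 rose and 0 fell when adjusted over the list alone. Its camera adjusted p was 0.00409, against an adjusted p = 0.402 with an estimated correlation. The hypoxia list, genes known to be induced by low oxygen, had 16 of 34 genes measured and a median log2 fold change of -0.89, with negative values in 14 of 16. None of the 16 passed over all probe sets and 2 fell when adjusted over the list alone. The member with the widest difference was AT1G19530, at a log2 fold change of -2.18 ± 0.88 (SE, adjusted p = 0.204 from limma). The list's camera adjusted p was 0.00409, against an adjusted p = 0.402 with an estimated correlation, and 0.101 without control replicate 3. The list of oxidative stress and detoxification genes had 8 of 37 genes measured, a median of 0.71 and positive values in 6, and none passed over all probe sets or over the list alone. Its leading member was STZ (AT1G27730), a zinc finger transcription factor, at a log2 fold change of 1.41 ± 0.46 (SE, limma adjusted p = 0.118). The camera adjusted p of that list was 0.0350, with an adjusted p = 0.402 with an estimated correlation, 0.128 without SNP replicate 2, 0.0597 without SNP replicate 3, 0.0891 without control replicate 1 and 0.0917 with each array centred on its median. For all of these lists the control and SNP arrays also differed in the control probe sets. The mean bioC signal was 6.32 against 8.53. The ranges of bioC, bioB, bioD, cre, dap, thr and phe did not overlap between these groups.

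The remaining lists did not pass or were too small to test. PORB (AT4G27440), which reduces protochlorophyllide in chlorophyll synthesis, rose by 1.88 ± 0.20 (SE) on the log2 scale, and the tetrapyrrole list of 7 measured genes had a camera adjusted p of 0.0525. That list passed without cPTIO replicate 1 (0.0474), cPTIO replicate 3 (0.0436), SNP replicate 2 (0.0131) or control replicate 1 (0.0236), and with the replicate number as a block (0.0383). Among 8 measured iron deficiency genes, AT1G74770, the BRUTUS-like ubiquitin ligase BTSL1, fell by 2.16 ± 0.25 and BGLU42 (AT5G36890) rose by 0.65 ± 0.13, with a camera adjusted p of 0.822 for the list. Of 9 measured auxin genes, HAT2 (AT5G47370), a homeodomain transcription factor, fell by 1.91 ± 0.42, and the list had a camera adjusted p of 0.927. BGLU42 and HAT2 lost their calls without SNP replicate 1, SNP replicate 2 or control replicate 2, and BGLU42 also without control replicate 3 and HAT2 without SNP replicate 3, with adjusted p values of up to 0.100 and 0.128. The heat shock list of 6 genes (adjusted p = 0.210), the mitochondrial list of 5 (0.238) and the photosystem and Calvin cycle list of 8 (0.958) did not pass and had no called member. Their leading values were 0.95 ± 0.59 for AT1G53540, a small heat shock protein, -1.43 ± 0.39 for AT2G21640 and -0.42 ± 0.16 for SBPASE (AT3G55800). All 3 measured root hair markers fell. The peroxidase AT4G26010 fell by 2.59 ± 0.35, the expansin EXPA18 (AT1G62980) fell by 1.28 ± 0.18 and the expansin EXPA7 (AT1G12560) fell by 0.98 ± 0.18, the last with adjusted p values of 0.0571, 0.0634 and 0.0607 without control replicates 1, 2 and 3. The single measured gene of the NO list, AT3G52960, the chloroplast peroxiredoxin PRXIIE, rose by 0.73 ± 0.11.

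In total 1409 of 22746 probe sets passed an adjusted p of 0.05 with SNP, 585 higher and 824 lower, and of these 745 carried a single gene name. With each array centred on its median, 815 were higher and 713 lower. The count depended on single arrays, being 671, 500 and 936 without SNP replicate 1, 2 or 3, 895, 516 and 826 without control replicate 1, 2 or 3, and 2542 without cPTIO replicate 3, which enters through the shared estimate of the spread. With only the 6 arrays compared it was 2440.

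The comparison of cPTIO with the control asks which transcripts differ in seedlings given an NO scavenger. The data used here hold no NO levels. AT5G20790 rose by 3.33 ± 0.75 (SE) on the log2 scale, from 4.02 ± 0.96 to 7.35 ± 1.03 (SD, n = 3 each). AT3G26510 rose by 2.42 ± 0.30, AT3G15450 of the aluminium-induced protein family by 2.33 ± 0.53, the aspartyl protease family member AT5G19120 by 2.13 ± 0.25, AT2G04050, the efflux carrier DTX3, by 2.00 ± 0.40, AKINBETA1 (AT5G21170), a beta subunit of the SnRK1 energy-sensing kinase, by 1.96 ± 0.45, AT4G35750 by 1.95 ± 0.35 and the ubiquitin ligase RING1 (AT5G10380) by 1.88 ± 0.18. The cupin AT4G36700 fell by 3.44 ± 0.63 and AT5G62360 fell by 2.67 ± 0.28, both also among the largest falls with SNP. The plastid-encoded ribosomal protein gene rpl16 fell by 3.04 ± 0.28, and AT1G47400, encoding the iron-responsive peptide IMA1, fell by 2.57 ± 0.33, from 9.27 ± 0.46 to 6.70 ± 0.25 (SD, n = 3 each). CYP71B26 (AT3G26290) fell by 2.18 ± 0.32, the histone H2B gene AT2G28720 fell by 2.14 ± 0.21, AT2G01870 fell by 2.13 ± 0.16 and the class III peroxidase AT1G34510 fell by 2.11 ± 0.46. Several of these genes also differed between SNP and control arrays. For example, rpl16 was at 7.77 to 8.00 with SNP and 10.3 to 10.5 in the control, and AT3G26510 at 8.51 to 9.59 and 6.87 to 7.23. For others, such as AT1G47400 (8.33 to 9.47 and 8.74 to 9.63), those arrays overlapped. Limma adjusted p values of the 16 genes lay between 0.00294 and 0.0414. For 7 of the 16 the call held with each of the 9 arrays left out. AT5G20790, AT3G15450, AT2G04050, AKINBETA1, AT4G35750, AT4G36700, AT1G47400, CYP71B26 and AT1G34510 lost it without control replicate 2, with adjusted p values of 0.122, 0.129, 0.107, 0.131, 0.0732, 0.0944, 0.0511, 0.0613 and 0.132. AT1G47400 and CYP71B26 lost it without that array alone. AT4G36700 also lost it without control replicate 3, AT4G35750 without any control array, AT2G04050 without any control array or cPTIO replicate 2, AT3G15450 without any control array, cPTIO replicate 1 or 3 or SNP replicate 1, and AT1G34510 without any control array, cPTIO replicate 1 or 3 or SNP replicate 2. AKINBETA1 lost it without any array but cPTIO replicate 2 and SNP replicate 3, and AT5G20790 without any array but SNP replicate 3.

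Of the 9 lists tested, 1 passed with cPTIO. The iron deficiency list, genes known to be induced when iron is short, had 8 of 34 genes measured and a median log2 fold change of -0.78, with negative values in 7. AT1G47400 and AT1G74770 fell, the latter by 1.05 ± 0.25 (SE), and 6 did not pass; 2 fell and 0 rose when adjusted over the list alone. The camera adjusted p was 0.0161, against an adjusted p = 0.215 with an estimated correlation, and it was 0.101 without cPTIO replicate 1. The call of AT1G74770 was lost without any array but cPTIO replicate 2 and SNP replicate 3, with adjusted p values of up to 0.136 (without cPTIO replicate 1). The hypoxia list had a median of 0.53 with positive values in 11 of 16, and 2 members rose, 4 when adjusted over the list alone. These were AT4G27450, of the same family as AT3G15450, by 1.83 ± 0.36 and the pyruvate decarboxylase PDC2 (AT5G54960) by 0.86 ± 0.16, both lost without control replicate 2 (adjusted p = 0.100 and 0.0950) or cPTIO replicate 1 (0.0822 and 0.0738) from limma, the former also without control replicate 1 (0.0639) and the latter without control replicate 3 (0.0674). That list's camera adjusted p was 0.0756, and it was 0.0139 without cPTIO replicate 3, 0.0361 without control replicate 2, 0.00227 without control replicate 3, 0.0392 after a second quantile normalization and 0.0362 without the probe sets of lowest signal. As with SNP, the control and cPTIO arrays differed in the bioC signal, 6.32 against 8.36.

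In the other lists PORB rose by 1.18 ± 0.20 (SE) on the log2 scale, and WES1 (AT4G27260), the auxin-conjugating enzyme GH3.5, rose by 1.67 ± 0.33, and both lost their calls without control replicate 2 (adjusted p = 0.0791 and 0.112 from limma) or cPTIO replicate 1 (0.0576 and 0.0698), WES1 also without control replicate 1 (0.0735). DTX3, listed among the detoxification genes, was the member of that list that rose, and 7 did not pass. DFR (AT5G42800), the dihydroflavonol reductase of anthocyanin synthesis, was at a log2 fold change of -2.30 ± 0.64 (limma adjusted p = 0.0715), and none of the 8 measured genes of its list passed. Of the root hair markers EXPA18 fell by 0.79 ± 0.18, while EXPA7 and AT4G26010 were at -0.49 (adjusted p = 0.143) and -1.04 (0.121). The EXPA18 call was lost without any array but SNP replicate 3, with adjusted p values of up to 0.108. AT3G52960 rose by 0.75 ± 0.11, and its adjusted p was 0.0619 without control replicate 2. The camera adjusted p values of the phenylpropanoid, photosystem and tetrapyrrole lists were 0.376, that of the auxin list was 0.391, and those of the detoxification, heat shock and mitochondrial lists were 0.455. No member of the photosystem, heat shock or mitochondrial lists passed, and the leading values in them were 0.25 ± 0.09 for PSBY (AT1G67740), 0.82 ± 0.59 for AT1G53540 and -1.35 ± 0.39 for AT2G21640.

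With cPTIO 1498 probe sets passed, 527 higher and 971 lower, and 857 of them carried a single gene name. With each array centred on its median, 753 were higher and 772 lower. The count was 122 without control replicate 2, 824 and 630 without control replicate 1 or 3, 420 without cPTIO replicate 1, and 847 and 782 without SNP replicate 1 or 2. With only the 6 arrays compared it was 280, of which 275 were among the 1498. The fit of all arrays shares 1 estimate of the spread among the groups. Correlations within groups reached lower with cPTIO (0.963 to 0.989) than with SNP (0.986 to 0.994) or in the control (0.987 to 0.993). The errors given for comparisons with cPTIO may therefore be too small.

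The comparison of SNP with cPTIO sets the NO donor against the NO scavenger and does not use the control arrays except for the estimate of the spread. DFR was higher with SNP, at 9.01 ± 0.92 against 5.01 ± 0.47 on the log2 scale (SD, n = 3 each), a log2 fold change of 4.00 ± 0.64 (SE). AT4G14090 was higher by 3.37 ± 0.47 and UF3GT (AT5G54060), an anthocyanin glycosyltransferase, by 2.81 ± 0.59. AT2G47780 was higher by 4.24 ± 0.59, AT3G28220 by 3.53 ± 0.27, AT1G52000 by 2.52 ± 0.53, AT1G73120 by 2.50 ± 0.24 and AT2G43530 by 2.49 ± 0.28. The peroxidases AT3G01190 and AT4G11290 were lower with SNP, at log2 fold changes of -3.22 ± 0.34 and -2.61 ± 0.36. Lower too were the lipid transfer protein gene AT2G48130 (-3.22 ± 0.27), AT3G16670 (-3.11 ± 0.24), AT4G16260 (-2.85 ± 0.25), AT4G27450 (-2.82 ± 0.36), AT4G38080 (-2.77 ± 0.28) and AT4G15390 (-2.71 ± 0.43). The limma adjusted p values of the 16 genes lay between 0.00145 and 0.0441. For 9 of the 16 the call held with each of the 9 arrays left out, whereas AT2G47780, DFR, UF3GT, AT1G52000, AT4G15390 and AT4G11290 lost it without SNP replicate 2 (adjusted p = 0.0571, 0.0871, 0.146, 0.171, 0.0731 and 0.0551) and AT4G14090 without SNP replicate 1 (0.0509). AT4G11290 lost it without that array alone, AT2G47780 also without SNP replicate 1, DFR and AT4G15390 also without SNP replicate 1 or cPTIO replicate 1, UF3GT without any array but SNP replicate 3 and control replicate 1, and AT1G52000 without any array but SNP replicate 3. The values of AT1G52000 and AT4G14090 without SNP replicate 3 were 3.25 and 3.97, and that of AT2G47780 without cPTIO replicate 1 was 4.88, shifts of over 1.5 times in fold.

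Of the 9 lists tested, 2 passed. The 2 groups also differed in a measure of RNA quality, as the mean 3' minus 5' difference of the housekeeping probe sets was 1.18 to 1.33 on the log2 scale in the SNP arrays and 1.11 to 1.12 in the cPTIO arrays. The hypoxia list had a median log2 fold change of -1.26, with negative values in 15 of 16 genes. AT4G27450, AT1G33055 (HUP32, at -2.58 ± 0.52, SE) and AT3G03270 (HRU1, a universal stress protein family member, at -0.98 ± 0.17) fell, 13 did not pass, and 9 fell when adjusted over the list alone. Per array the mean deviation of the 16 genes from their means over all arrays was -0.95 to -0.64 with SNP and 0.28 to 0.87 with cPTIO, against -0.53 to 0.82 in the control. The camera adjusted p was 4.23e-08, with an adjusted p = 0.263 with an estimated correlation and 0.0388 in fry. The phenylpropanoid, flavonoid and anthocyanin list had a median of 1.38 with positive values in 7 of 8 genes. DFR, AT4G14090 and UF3GT rose and 5 did not pass, against 4 that rose when adjusted over the list alone. Its camera adjusted p was 5.17e-05, again with an adjusted p = 0.263 with an estimated correlation and 0.0388 in fry. Of that list SNP replicate 3 had a mean deviation of 0.14, whereas SNP replicates 1 and 2 had 1.22 and 1.53. Both lists passed without each of the 9 arrays. The calls of AT1G33055 and AT3G03270 were lost without SNP replicate 2 (adjusted p = 0.159 and 0.109 from limma), and also without SNP replicate 1 or cPTIO replicate 1 or 2, and for AT1G33055 without SNP replicate 3 or control replicate 2.

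**Figure D3:**
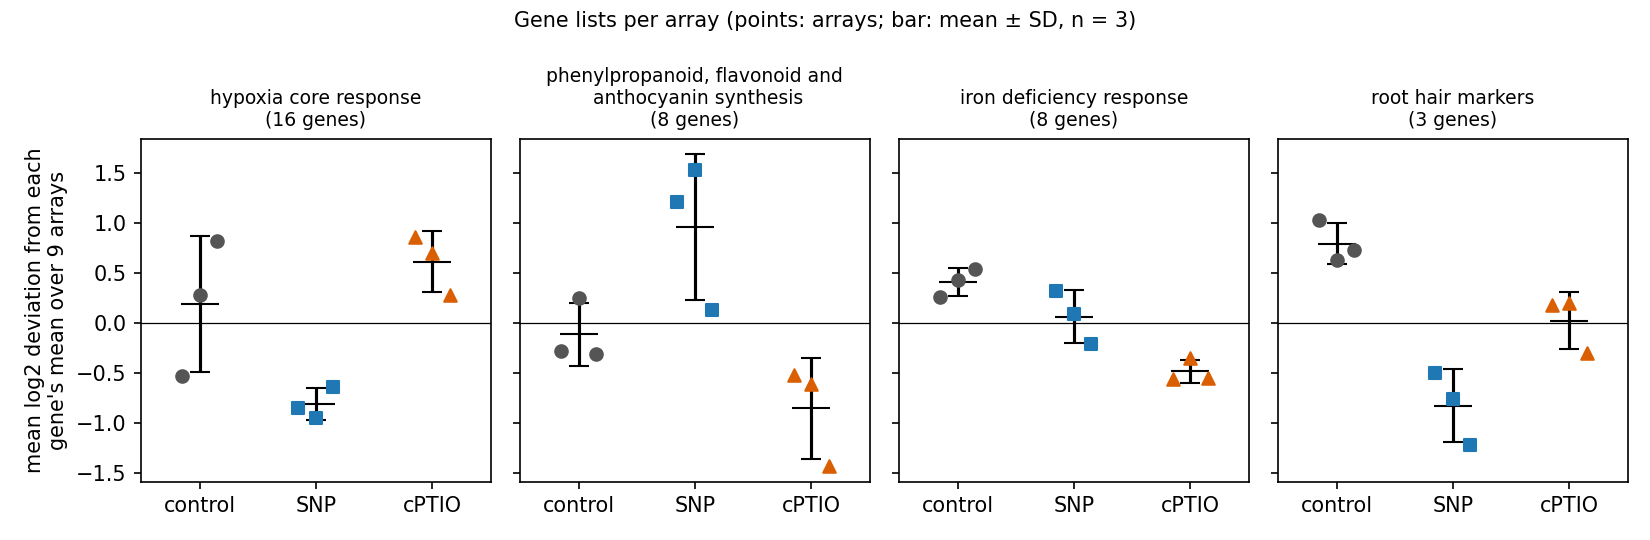
Mean log2 deviation of the genes of 4 lists from their means over all 9 arrays (vertical) in the 3 groups (horizontal); points are arrays and bars the mean ± SD with n = 3. The hypoxia list lies from -0.95 to -0.64 in the SNP arrays and from 0.28 to 0.87 in the cPTIO arrays, and the 3 root hair markers lie from 0.63 to 1.03 in the control arrays and below 0.2 in all treated arrays.

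The iron deficiency list had a median of 0.41 and a camera adjusted p of 0.0594, with AT1G47400 higher with SNP by 2.32 ± 0.33 (SE) and BGLU42 by 0.80 ± 0.13, and 6 genes that did not pass. That list passed without SNP replicate 3 (0.0184), control replicate 1 (0.0477), control replicate 2 (0.0499) or replicate 3 of both treatments (0.0287), with each array centred on its median (0.0492), with the mean of all probe sets of a gene (0.0491) and in fry (0.0388). It did not pass in the other alternatives, with the highest values at 0.263 with an estimated correlation, 0.178 without the probe sets of lowest signal and 0.154 without cPTIO replicate 1. AT1G47400 and BGLU42 lost their calls without SNP replicate 2 (adjusted p = 0.0588 and 0.0871 from limma) and BGLU42 also without SNP replicate 1 (0.0682). Among the detoxification genes GSTU25 (AT1G17180), a glutathione transferase, was higher by 1.95 ± 0.34, and that list had a camera adjusted p of 0.294, or 0.00796 without cPTIO replicate 3. Among the mitochondrial genes the NADH dehydrogenase NDB2 (AT4G05020) was lower, at -0.54 ± 0.11, with a list p of 0.607. GSTU25 lost its call without SNP replicate 2 (0.116), SNP replicate 3, cPTIO replicate 1 or control replicate 2, and NDB2 without SNP replicate 1 (0.127) or any other array but control replicates 1 and 3. No member of the tetrapyrrole, auxin, heat shock or photosystem lists passed, and their camera adjusted p values were 0.294, 0.294, 0.463 and 0.268; the heat shock list alone passed without cPTIO replicate 1 (0.0190). The leading values in them were 0.83 ± 0.33 for CHLI2 (AT5G45930), -0.91 ± 0.42 for HAT2, 0.49 ± 0.50 for AT5G37670 and -0.41 ± 0.16 for SBPASE. The root hair markers AT4G26010, EXPA18 and EXPA7 were at -1.56 (adjusted p = 0.0551 from limma), -0.49 (0.198) and -0.49 (0.195).

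Between SNP and cPTIO 742 probe sets passed, 381 higher and 361 lower with SNP, and 367 of them carried a single gene name. With the replicate number as a block on the 6 SNP and cPTIO arrays alone, 282 passed, 114 higher and 168 lower, and 225 of the 742 were among them. On those arrays without the block 267 passed, 104 higher and 163 lower. Of the 742 in the fit of all arrays, 137 were higher and 211 lower at a minimum of 2-fold. The near-even balance thus held for all 742 together, and not for their 2-fold part or for the fits on 6 arrays. With that block on 6 arrays both lists above still passed. With that block UF3GT, AT1G52000, AT4G15390, AT4G11290, AT3G03270, GSTU25, NDB2 and BGLU42 did not pass (adjusted p = 0.0700, 0.108, 0.0580, 0.0659, 0.0536, 0.0713, 0.101 and 0.0655). The block was added after the data were seen. The count was 220 and 161 without SNP replicate 1 or 2, 359 without cPTIO replicate 1, 1313 without cPTIO replicate 3, and 423 and 494 without control replicate 2 or 3.

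Whether the donor and the scavenger moved transcripts in opposite or like directions was read from both comparisons with the control. Of the probe sets called in both, 525 of 537 had moved the same way. There were 175 higher in both and 350 lower in both, where independent lists of those sizes would share 13.6 and 35.2. Only 4 were higher with SNP and lower with cPTIO and 8 the other way, where independent lists would share 25.0 and 19.1. Those named among the 12, singled out after their values were seen, were GPDHC1 (AT2G41540), AT4G15830, scpl29 (AT4G30810) and AT1G75900, which rose with SNP and fell with cPTIO, and AT5G62340, AT5G23830, AT3G51330, MSRB9 (AT4G21850) and AT3G05920, which did the reverse. AT3G51330, for example, was at log2 fold changes of -1.20 ± 0.14 (SE) with SNP and 0.90 ± 0.14 with cPTIO. Across probe sets the fold changes correlated at 0.573, against a mean of 0.362 in 100 simulations of unchanged groups set against the same control spread. Their covariance was 0.101, against a simulated mean of 0.0147 and a highest simulated value of 0.0166. Those simulations took genes and arrays as independent. In 1000 others that kept the correlation between genes and the pairing of SNP and cPTIO arrays, the mean covariance was 0.0226, the highest 0.145 and the mean correlation 0.598, and 4 reached the covariance measured. The 3 control arrays were too few to be divided, so part of the overlap may come from their being shared, and all of these values also hold the difference in bioC signal between control and treated arrays.

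**Figure D4:**
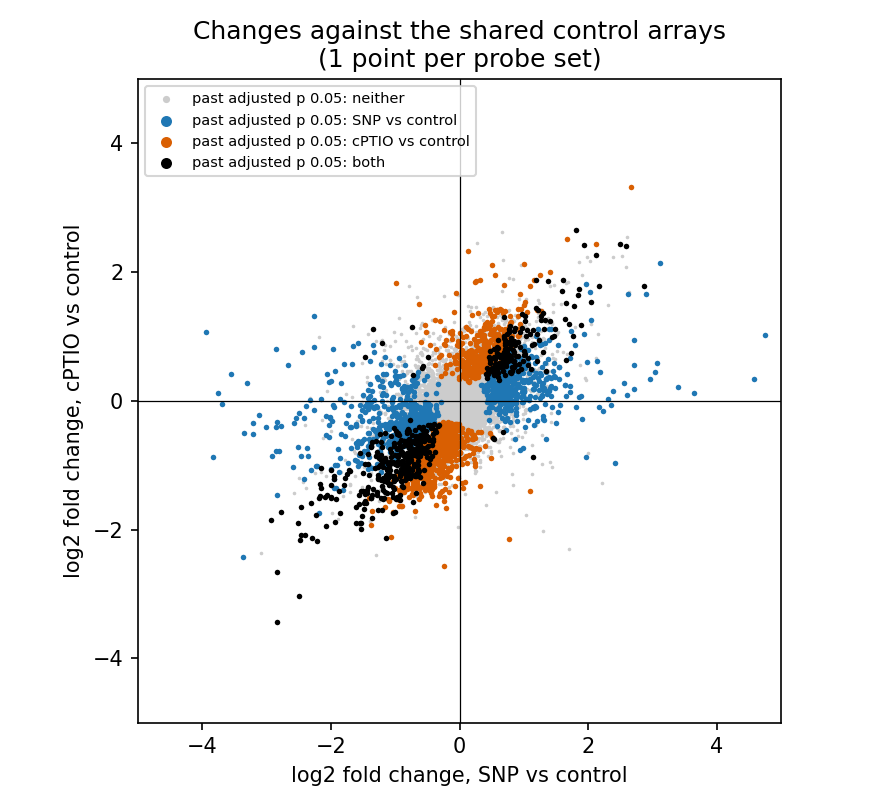
Log2 fold change against the shared control arrays with SNP (horizontal) and with cPTIO (vertical), 1 point per probe set, coloured by which comparison it passed at an adjusted p of 0.05. Of the probe sets past both thresholds, 525 of 537 lie in the quadrants where both changes have the same sign.

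A single test over the 3 groups, the moderated F test of limma, was passed by 2227 probe sets. That count was 3545 without cPTIO replicate 3, 744 without control replicate 2, 1390 and 1130 without control replicate 1 or 3, 1052 and 812 without SNP replicate 1 or 2, and 1431 without cPTIO replicate 1.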

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

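Of the tests in this part, those of the hybridisation controls, of RNA integrity in all 3 patterns, of GI and of the shared controls with pairing were chosen after the values had been seen; the others were fixed before.

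The bioC control probe sets, which belong to no comparison of seedling transcripts, were higher in all 6 treated arrays than in all 3 control arrays, by a mean of 2.12 on the log2 scale. The means were 8.45 ± 0.34 (SD, n = 6) and 6.32 ± 0.18 (SD, n = 3). The dap, thr and phe control probe sets were also higher in the treated arrays on average, by 1.00, 0.51 and 0.42, with overlapping ranges. The SNP arrays taken alone did not overlap the control arrays in these families or in bioB, bioD and cre.

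SNP and cPTIO arrays had moved the same way against the control arrays in 525 of the 537 probe sets called in both comparisons. Sharing the control arrays may account for part or all of the covariance of the fold changes, which was 0.101. It was above the highest of 100 simulations that took genes and arrays as independent, 0.0166, but not above the highest of 1000 that kept the correlation between genes and the pairing of SNP and cPTIO arrays, 0.145, of which 4 reached it. A difference in RNA integrity is argued against, because the mean 3' minus 5' difference of 6 pairs of housekeeping probe sets lay inside the range of the treated arrays (1.11 to 1.33) for 2 of the 3 control arrays. The control arrays, at 1.28, 1.09 and 1.25, lay on both sides of the cPTIO range of 1.11 to 1.12, and 2 of them inside the SNP range of 1.18 to 1.33. A separate hybridisation of the control arrays cannot be told apart from the treatments: the highest control array had a bioC mean of 6.50 and the lowest treated array 7.77. A response shared by both treatments, such as to the handling of the dishes, also stays open and was not tested.

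Replicate 3 of SNP and replicate 3 of cPTIO deviated together from their groups, with a correlation of 0.42 across probe sets. Degradation of both RNA samples was not shown and stays open. Both arrays had the highest 3' minus 5' difference of their own group, but both gaps were within the spread of the other arrays. The values were 1.334 against 1.324 at most in the other SNP arrays and 1.119 against 1.116 in the other cPTIO arrays. The cPTIO replicate 3 value also lay below the lowest SNP array, 1.184. Another time of day at collection may account for it as a hypothesis, since GI (AT1G22770), a clock gene with a strong daily rhythm, was at 3.14 and 3.47 in these 2 arrays and between 4.52 and 5.62 in the other 7. GI was the only measured gene of the 20 in the clock list, and 1 gene outside the range in 2 arrays cannot settle the question.

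The hypoxia list was lower with SNP than with cPTIO. No single array accounts for it, since the camera adjusted p was at most 4.90e-06 in the 9 fits without 1 array (without cPTIO replicate 2). A shift of genes with a like expression level is argued against by the median log2 fold change of -1.26, as 95% of 10000 random lists of 16 genes matched on mean expression lay between -0.17 and 0.22. The p of 0.263 with an estimated correlation leaves open how far 16 genes that move together count as separate evidence. A difference in RNA integrity cannot be told apart from the treatments, since the lowest SNP array had a 3' minus 5' difference of 1.18 and the highest cPTIO array 1.12, and within groups the list mean had a slope of -0.87 ± 2.56 (SE) on that difference over 9 arrays. Candidate explanations such as NO itself, other volatile products of SNP or the liquid added to the dishes of the cPTIO seedlings are confounded by the design. They were not tested.

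The split of the arrays into groups was set against other splits. Of 100 splits of the 9 arrays into 3 groups of 3, only the real one reached 2227 probe sets in the F test. The highest of the others gave 541. Chance would be excluded for that count only if the arrays were freely exchangeable, and the pairing of SNP and cPTIO arrays goes against that. Of the 42 of these splits that parted all 3 pairs of same-numbered SNP and cPTIO arrays, 1 gave as many, the real one, and the highest of the others gave 284. The split with 541 also kept the 3 control arrays together. For pairs of groups 10 splits of 6 arrays are too few for a share under 0.05. The real splits gave 1409, 1498 and 742 probe sets for SNP against control, cPTIO against control and SNP against cPTIO, each reached by 1 split of the 10, the real one, and the highest of the other splits gave 0 in each case with limma. At an unadjusted p under 0.05 the other splits gave up to 908, 1939 and 2014 probe sets, against 4739, 5404 and 4138 for the real ones. For SNP against cPTIO, where the numbers were taken to pair the arrays, 4 splits parted all 3 pairs, and the 3 others gave 0.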

How the results depend on the processing

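The block on the 6 SNP and cPTIO arrays alone and the removal of replicate 3 of both treatments were chosen after the data were seen. No called named gene changed sign with the 2 scalings or any array left out. The blocks, the filter and the fit of only the arrays compared leave fold changes as they are by construction, so they cannot test the sign. The largest rises and falls were chosen without overlap between groups, so leaving out an array could not change their sign either. Calls were lost, however. Of 79 named calls, 20 were lost with only the arrays compared, 1 after second quantile normalization and 2 after median centring. Leaving out 1 array lost between 9 (without SNP replicate 3) and 37 (without control replicate 2) of the 79. The block on the 6 SNP and cPTIO arrays lost 10 of the 24 named calls between those groups. With the filter 2 of the 78 named calls still in the data were lost. Array weights and the prior settings were run for counts alone. Counts stayed within 1.5 times of the reported ones with the replicate block over 9 arrays (1496, 1612 and 741 probe sets for SNP against control, cPTIO against control and SNP against cPTIO), second quantile normalization, median centring, the low-signal filter and the trended prior. That block ended the calls of APS3 in both comparisons with the control, AT5G20790 and AT1G74770 with cPTIO, and AT1G52000, AT1G33055 (adjusted p = 0.0711) and NDB2 between the treatments, and made calls of AT2G21640 in both comparisons with the control and AT4G26010 between the treatments.

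In the order given above, fitting only the arrays compared gave 2440, 280 and 267, array weights 3560, 2260 and 1652 (4389 in the F test), the 2-fold minimum 562, 469 and 348, and leaving out replicate 3 of both treatments 2256, 2330 and 1392 (3602 in the F test). The block on 6 arrays gave 282 between the treatments. Leaving out 1 array gave 500 to 2542, 122 to 2114, 161 to 1313 and, in the F test, 744 to 3545. The 2-fold minimum lowers counts by construction; the cause of the other shifts was not tested. The correlation of the SNP and cPTIO fold changes was 0.506 without these 2 arrays and 0.491 to 0.613 without 1 array. Lists past the test numbered 3, 1 and 2, and 0 in all 3 with an estimated correlation. Fry gave 0 for SNP against control. For cPTIO against control 2 passed after second quantile normalization, with the filter and without these 2 arrays, when 4 passed between the treatments. Without 1 array the ranges were 2 to 4, 0 to 2 and 2 to 3. The alternative for values not on a log scale did not apply. Signal over background could not be judged from these values.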

Other observations

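The families in this part were chosen after the data were seen, so their values describe these arrays and are not independent tests. Class III peroxidases, secreted enzymes of the cell wall, had 55 of 73 members measured. With SNP against the control 8 fell, 4 rose and 43 did not pass, with a median log2 fold change of -0.18 and a camera p of 0.0120, or p = 0.213 with an estimated correlation. AT4G11290, AT5G19890, AT3G01190 and AT4G26010 fell, at log2 fold changes of -3.01, -2.78, -2.67 and -2.59, while AT2G22420, AT5G51890, AT1G71695 and PRXR1 rose by 1.16, 1.07, 0.91 and 0.57. AT4G26010 is also 1 of the 3 measured root hair markers, of which EXPA18 and EXPA7 fell too, at -1.28 and -0.98, and the mean deviation of the 3 was -0.82 with SNP, 0.80 in the control and 0.03 with cPTIO. Against cPTIO 6 were lower with SNP and 2 higher, with a median of -0.15 and a camera p of 0.00105, or p = 0.119 with an estimated correlation. With cPTIO against the control 3 rose and 3 fell. In a test run only after several members had stood out, the medians of -0.18 and -0.15 lay outside the central 95% of 10000 random lists matched on mean expression, -0.08 to 0.05 in both cases, which takes no account of correlation between genes. A prediction written for that test was withdrawn after it had run, because a family picked for its members cannot test its own pattern. The mean deviation of the family was -0.36 to -0.17 in the SNP arrays, 0.12 to 0.21 in the control and -0.04 to 0.24 with cPTIO, and the median stayed negative in SNP against the control and against cPTIO under every scaling tried and without each array. Its size moved, to -0.09 without SNP replicate 2 and -0.68 without the probe sets of lowest signal against the control, and to -0.32 without cPTIO replicate 3, -0.29 without replicate 3 of both treatments and -0.44 without the probe sets of lowest signal against cPTIO.

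Genes encoded in the plastid genome had 69 members measured. With cPTIO against the control 19 fell and 0 rose, with a median log2 fold change of -0.39. They included rpl16, rpl20, rpl14, rps16, ndhK, psbZ and rbcL, of which rbcL, the large subunit of Rubisco, fell by 1.43 ± 0.30 (SE) on the log2 scale and psbZ, a photosystem II subunit, fell by 1.07 ± 0.12. With SNP against the control 4 fell, petL, rpl20, rpl16 and psbZ. Between the treatments 3 were higher with SNP, rpoC2, ycf3 and rps16, at a median over the 69 genes of 0.42. The same arrays differed in the 3' minus 5' difference of the housekeeping probe sets, 1.18 to 1.33 with SNP and 1.11 to 1.12 with cPTIO. For cPTIO against the control the camera p was 3.88e-11, or p = 0.0651 with an estimated correlation. For SNP against cPTIO the camera p was 3.47e-12, or p = 0.0553 with an estimated correlation. Both values with an estimated correlation fail a threshold of 0.05. The mean deviation was -0.48 and -0.44 in cPTIO replicates 1 and 2 and -0.02 in cPTIO replicate 3. SNP arrays lay between 0.01 and 0.21 and control arrays between 0.12 and 0.33. The medians kept their sign under every scaling tried and without each array, but that of cPTIO against the control was -0.60 without cPTIO replicate 3 and that of SNP against cPTIO 0.27 without cPTIO replicate 2.

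Single genes of the lists with under 5 measured members also passed. COR47 (AT1G20440), a dehydrin, was lower with SNP than in the control and with cPTIO, at log2 fold changes of -2.39 ± 0.38 (SE) and -2.31 ± 0.38, with adjusted p values from limma of 0.0509 and 0.0920 without SNP replicate 2, and 0.0867 against cPTIO with the block on the 6 treated arrays. COR15A (AT2G42540) rose by 0.75 ± 0.15 with SNP, while LHCB4.3 (AT2G40100), a light-harvesting protein, fell by 1.06 ± 0.22, WRKY53 (AT4G23810) fell by 1.21 ± 0.26 and AT1G68670 (HHO2) rose by 0.81 ± 0.17. COR15A and AT1G68670 lost their calls without SNP replicate 1 or 2 or control replicate 2 or 3 (adjusted p up to 0.100 and 0.112), and LHCB4.3 and WRKY53 without any SNP or control array (up to 0.0965 and 0.133). The sulphite reductase gene SIR (AT5G04590) rose by 0.64 ± 0.09 with cPTIO and was lower with SNP than with cPTIO, at -0.50 ± 0.09, and the ATP sulphurylase gene APS3 (AT4G14680) rose by 0.62 ± 0.14 with SNP and 0.59 ± 0.14 with cPTIO. SIR lost the first call without control replicate 2 (adjusted p = 0.0591) and the second without any SNP array, cPTIO replicate 1 or control replicate 3 (up to 0.111) and with the block (0.0973). APS3 lost the call with SNP without any control array, SNP replicate 1 or 2 or cPTIO replicate 2 (up to 0.139), and that with cPTIO without any array but SNP replicate 3 (up to 0.127). No measured member of the salicylic acid, jasmonate, cell cycle, glucosinolate, clock, stomatal, endodermis or seed storage lists passed in any comparison. Measured were 2 of 24 salicylic acid, 3 of 27 jasmonate and 3 of 32 cell cycle genes. Of the aliphatic and indole glucosinolate lists 2 of 17 and 1 of 11 were measured. For the clock, stomatal, endodermis and seed storage lists it was 1 of 20, 4 of 12, 1 of 27 and 2 of 19. So few genes cannot show that these responses were absent.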
